A study of Triticum aestivum with 16 samples.

How the data were processed

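Leaf RNA of the wheat varieties Emese (winter type) and Nadro (spring type), hardened at 5 °C under normal or low light, was hybridised to 16 oligonucleotide arrays with the dyes Cy3 (green) and Cy5 (red), 4 arrays to a slide. Conditions, dyes, replicate numbers and slides were taken from the labels, and each array was assigned from them alone. Each condition had 2 biological replicates, each an extract of 4 pooled technical replicates of 5 plants per the labels' protocols, and each pair of extracts was hybridised in both dye orientations. The slide numbers are 12 (replicate 1, second dye orientation), 13 (replicate 2, first), 14 (replicate 2, second) and 15 (replicate 1, first).

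Per the file headers, the scanner files hold the mean intensity and median local background of each spot in both channels, made by Agilent Feature Extraction. The same files hold processed intensity values which, per the file headers, were background subtracted, detrended and dye normalised by that software. They also hold a log10 ratio of red over green processed signal, per the file headers, which was used only to check the other columns. The series' value table was deposited as log2 ratios of red over green, normalised by the authors and centred on 0 for each array, as read from the values. The submitters' processing notes name R 2.10.0 and limma without saying which step each did, and how the background was treated is not stated.

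From the mean intensities, spots were corrected by normexp with an offset of 50, and each array's log2 ratio was normalised by loess with control spots given no weight. The offset pulls folds towards 0. On simulated data with known 4-fold changes the median estimated log2 was 1.34 over 16 arrays. Spots marked by the scanner software as non-uniform or as population outliers were left out and spots of the same probe averaged. Of 45220 features, 43803 were not controls, and they held 43603 probes. A probe was kept if it was well above background, as the scanner software marks it, in at least 6 of the 8 channels of at least 1 condition, which left 24834 probes. The value table had 0 columns without a sample.

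The 2 dye-swapped ratios of a pair were averaged, and the 4 ratios of a replicate's loop were solved by least squares into 4 extract values centred within the replicate. These 8 extract values were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0, data.table version 1.17.8), with 3 residual degrees of freedom and prior degrees of freedom of 1.41. The 5 comparisons were the light effect in each variety, the difference between varieties in each light, and the interaction. P-values are two-sided and were adjusted by Benjamini-Hochberg over 24834 probes for each comparison, with a threshold of 0.05. This fit, the gene lists, the choice of named genes and most alternatives were written down before the data were examined.

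Each array was compared with the mean ratio of other arrays for every pair of conditions. After 3 arrays of slide 15 were seen not to follow their label, a fit without that slide was added, here called the fit over 12 arrays. Replicate 1 is then held by slide 12 alone, in 1 dye orientation, so the dye effect of each probe was measured on the balanced arrays of replicate 2 and subtracted from replicate 1. Its prior degrees of freedom were 3.41. No array was given another label. Arrays, not extracts, were left out, so the number of extracts stayed at 2 per condition.

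In all, 31 gene lists were drawn by name, covering photosynthesis, cold regulation, sugar metabolism, stress and hormone pathways, protein synthesis and markers of other tissues, with 1 probe per gene. The 30 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all 150 tests, and again with the correlation estimated for each list. The preset correlation assumes that genes of a list are nearly independent, and 0 lists passed when it was estimated. That estimate rests on 3 residual degrees of freedom. The smallest adjusted p of camera was then 0.323 over 12 arrays and 0.810 over 16. A list that did not pass with it is therefore not shown to be unchanged. Informative names were available for 5631 of the kept probes. A table of reference sequences matched 851 probes of the array, but its symbols entered neither the lists nor the named genes. No genome coordinates were used.

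Genes named in the text follow 1 rule. Among kept probes with an informative name, 1 per gene name, past the threshold and of the same sign in both replicates and both dye orientations, the 10 largest rises and 10 largest falls of each comparison could be named. To these were added the 2 members with the smallest p of each list that passed or had at least 3 members past the threshold, and for the interaction the 10 smallest p. Where fewer than 5 probes passed, the 5 with the smallest p are named as not passing. The rule was applied to the fit over 16 and to that over 12 arrays, and the text names part of what it gives. Genes too dim in a condition for a fold to be more than a bound were left out of the text.

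Depth differed by slide: both channels were well above background for 48.1 to 55.4% of spots on slides 12 to 14 and for 37.2 to 38.9% on slide 15. At most 2 spots of an array were saturated. The code was tested on simulated data with changes placed in the light effect of Emese, where the fit over 16 arrays recovered 82.1% of 1.5-fold changes and all 2-fold changes with 4 false calls, and that over 12 arrays 73.1% and all, also with 4 false calls. All simulated arrays followed their labels, the noise was assumed, and 67 of 24834 probes changed by 1.5-fold. These shares check the code and do not give the power of the real 16 arrays. Alternatives covered the background correction, normalisation, filter, source of the values, model, prior, threshold, list members, arrays used and leaving out each extract.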

Results

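Gene expression was measured in leaves of 2 bread wheat varieties that had been hardened in the cold under normal or low light. Mv Emese (called Emese here) is a winter variety with high freezing tolerance, and Nadro is a spring variety with low freezing tolerance. Plants grew for 10 days at 20 °C by day and 18 °C by night and were then held at a constant 5 °C, either at a photon flux density of 250 or at 20 (given in the labels as mmol per square metre and second). The labels' protocol was followed for these temperatures, although the series' design text gives 18 °C, and the length of the cold period is not given in the sources used here. Each of the 4 conditions had 2 biological replicates, and each replicate was 1 extract pooled from 4 technical replicates of 5 plants. RNA was compared on 16 arrays with a dye pair (Cy5, red, and Cy3, green), 4 to a slide. The pairs ran in a loop of normal-light Emese against low-light Emese, low-light Emese against low-light Nadro, low-light Nadro against normal-light Nadro, and normal-light Nadro against normal-light Emese. Both replicates went round the loop in both dye orientations. The share of probes well above background was 38.4 to 64.3% of spots in the red channel and 41.9 to 58.7% in the green channel, and 24834 probes were tested. With 2 extracts per condition the number of extracts limits the precision, and an array adds only technical precision.

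A set of 3 arrays did not follow the pair of conditions in their label, and all of them were on slide 15, which carried the first dye orientation of replicate 1. The array labelled normal-light against low-light Emese ran against the other arrays of that pair, with a correlation across probes of −0.829. The array labelled low-light Emese against low-light Nadro correlated with its pair at 0.114, and the array labelled low-light against normal-light Nadro at 0.214. The remaining array of that slide correlated with its own pair at 0.861. On the other 12 arrays the pair in the label was in every case the pair the array matched best, at 0.638 to 0.986. These correlations are across probes, which are not independent replicates. Slide 15 was also dimmer, with 38.4 to 43.6% of red spots well above background against 55.5 to 64.3% on the other slides. Every comparison was therefore also fitted over the 12 arrays of slides 12, 13 and 14, a choice made after seeing the data. The p-values of those 12 arrays are conditional on that choice and come out too small to the extent that it favoured arrays that resemble each other. In the fit fixed before the data were examined, with all 16 arrays as labelled, 0 probes passed the limma test at an adjusted p of 0.05 in any comparison. Below, "rose", "fell", "higher" and "lower" are used of the test over 12 arrays, and the value over 16 arrays stands beside it.

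**Figure D1:**
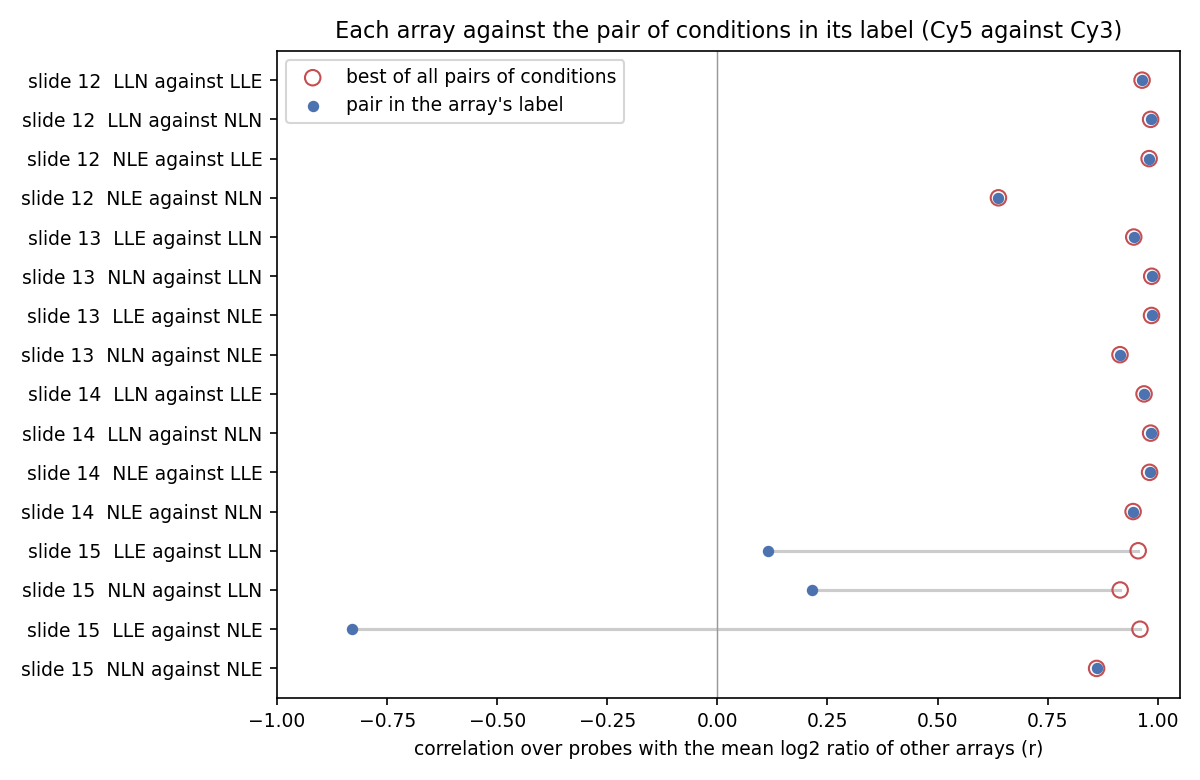
Correlation across probes (r, horizontal axis) of each of the 16 arrays with the log2 ratio fitted to other arrays of slides 12 to 14. Filled symbols give the pair of conditions in the array's label and open symbols the best of all pairs. NLE and LLE are normal-light and low-light Emese, NLN and LLN the same for Nadro. The 12 arrays of slides 12 to 14 sit at 0.638 to 0.986 with both symbols together, and 3 arrays of slide 15 sit at −0.829, 0.114 and 0.214 for their label and at 0.915 to 0.960 for another pair.

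In cold-hardened Emese, the genes with the largest rise under normal against low light included PsbS, chalcone synthase 1 and the fructan enzymes 6-SFT and 1-SST. The log2 ratio of normal over low light (± SE, n = 2 extracts per condition) was 5.60 ± 0.19 for PsbS (3.51 over 16 arrays), the photosystem II protein needed for heat dissipation of excess light. It was 5.34 ± 0.07 for chalcone synthase 1 (3.30), the entry enzyme of flavonoid synthesis. Of the fructan enzymes, 6-SFT (sucrose:fructan 6-fructosyltransferase) was at 5.32 ± 0.10 (3.16) and 1-SST (sucrose:sucrose 1-fructosyltransferase) at 5.03 ± 0.13 (3.17). The low molecular mass early light-inducible protein rose by 5.06 ± 0.08 (3.44), asparaginase by 4.72 ± 0.08 (3.33) and the fasciclin-like protein FLA15 by 4.47 ± 0.06 (3.03). On the other side, ASN1, an asparagine synthetase, was at −5.05 ± 0.04 (−3.25). Also among the largest falls were the thaumatin-like protein TLP4 at −4.65 ± 0.09 (−2.89), a beta glucanase at −4.63 ± 0.07 (−3.04), the xylanase inhibitor TAXI-IV at −4.43 ± 0.06 (−2.79) and chitinase 1 at −4.21 ± 0.06 (−2.60). The list of pathogenesis-related and defence genes did not pass (37 rose and 52 fell of 108, 38 and 56 adjusted over the list alone; camera adjusted p = 0.376 over 12 and 0.496 over 16 arrays, and adjusted p = 0.722 with an estimated correlation) and holds 36 members matched only inside another word, such as thionin in methionine. Without them 19 rose and 36 fell of 72 (20 and 39 adjusted over the list alone; median −0.19, camera adjusted p = 0.0674 over 12 and 0.327 over 16 arrays). Nor did that of fructan and soluble sugar genes (23 rose and 13 fell of 43, the same adjusted over the list alone; median 0.37 and 0.21, camera adjusted p = 0.0917 and 0.256, and adjusted p = 0.497 with an estimated correlation). Of these genes PsbS had the largest adjusted p over 12 arrays, 1.45e-06, and 6-SFT the largest over 16 arrays, 0.236.

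By groups, all 14 measured photoprotection and early light-induced genes rose in Emese (median log2 1.30 over 12 arrays and 0.85 over 16; camera adjusted p = 2e-06 and 0.000279), and 14 did so adjusted over the list alone. The adjusted p was 0.351 with an estimated correlation. Of 97 genes of the photosystems and electron transport, 56 rose and 14 fell (57 and 14 adjusted over the list alone; median 0.21; camera adjusted p = 1.89e-05, and adjusted p = 0.323 with an estimated correlation). Of 19 Calvin cycle genes, 13 rose and 1 fell over all probes and over the list alone, with a median of 1.30 (0.56 over 16 arrays), a camera adjusted p of 0.00155 (0.0518 over 16 arrays, which does not pass) and an adjusted p = 0.323 with an estimated correlation. Phosphoribulokinase, which regenerates the carbon dioxide acceptor, rose by 2.01 ± 0.08 (1.18). Light-harvesting genes as a list passed as lower under normal light over 16 arrays (median −0.21, camera adjusted p = 0.00195, and adjusted p = 0.810 with an estimated correlation) but not over 12 arrays (3 rose and 18 fell of 40, 2 and 17 adjusted over the list alone; median −0.09, camera adjusted p = 0.072, and adjusted p = 0.514 with an estimated correlation). The list's median was −0.14, −0.10 and −0.11 on slides 12, 13 and 14, and −0.45 on slide 15, whose array of this pair was off its label. Within that list a chlorophyll a/b-binding protein fell, at −1.90 ± 0.07 (−1.56). The chlorophyll synthesis list likewise passed as lower over 16 arrays alone (median −0.16, camera adjusted p = 0.0128, and adjusted p = 0.810 with an estimated correlation). Cold-regulated, dehydrin and LEA genes fell, 47 of 73 against 7 that rose (47 and 7 adjusted over the list alone), with a median of −0.59 (−0.30 over 16 arrays; camera adjusted p = 2.11e-05, and adjusted p = 0.546 with an estimated correlation). Ice recrystallization inhibition protein 1, which limits the growth of ice crystals, was at −3.06 ± 0.07 (−1.89). Phenylpropanoid and flavonoid genes rose, 23 of 38 against 8 that fell (the same counts adjusted over the list alone; median 0.52, camera adjusted p = 0.000439, and adjusted p = 0.323 with an estimated correlation). Cytosolic ribosomal protein genes fell, 108 of 135 against 5 (108 and 5 adjusted over the list alone), with a median of −0.44 (−0.25 over 16 arrays; camera adjusted p = 2.01e-11, and adjusted p = 0.351 with an estimated correlation). In the same comparison, markers of dividing cells fell, 39 of 56 against 6 (the same over the list alone; median −0.28 and −0.19 over 16 arrays, camera adjusted p = 9.07e-05, and adjusted p = 0.323 with an estimated correlation). Histone H1 WH1B.1 was at −1.66 ± 0.05 (−1.17). Vascular and cell wall markers rose, 44 of 68 against 13 (the same over the list alone; median 0.27 and 0.21, camera adjusted p = 0.000126, and adjusted p = 0.457 with an estimated correlation). FLA3 was at 2.84 ± 0.04 (1.78). A change in the share of such cells was not separated from a change within cells.

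Over 12 arrays 16491 probes passed in Emese, 7917 higher under normal light and 8574 lower, of which 1336 and 934 by at least 2-fold. Over 16 arrays 0 passed in limma, 7055 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.163. Named genes with the smallest p over 16 arrays, which did not pass, were zip1 (a leucine zipper protein, log2 −0.93 ± 0.06), protochlorophyllide reductase B (−0.87 ± 0.06), PsbO (−0.72 ± 0.05), a chloroplast recA homolog (0.65 ± 0.06) and FLA22 (0.75 ± 0.07). The slide 15 array with this label matched the light effect in Nadro with its sign reversed (0.96). That can favour genes whose light effects are opposite in the 2 varieties. The rankings over 16 arrays in the other comparisons likewise include the arrays off their label. Without low-light Emese replicate 1 the count over 12 arrays was 9242, the only left-out extract that moved it by more than 1.5 times.

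In cold-hardened Nadro, 3 fructan enzymes, PsbS and chalcone synthase 1 were the named genes with the largest rise under normal light. 6-SFT rose by 6.88 ± 0.10 on the log2 scale (4.72 over 16 arrays), 1-FFT (fructan:fructan 1-fructosyltransferase) by 6.01 ± 0.27 on 1 probe (2.55) and 4.90 ± 0.06 on another (3.71), and 1-SST by 5.78 ± 0.13 (3.76). PsbS rose by 5.85 ± 0.19 (3.68), chalcone synthase 1 by 5.51 ± 0.07 (3.57) and the high molecular mass early light-inducible protein by 3.94 ± 0.05 (2.45). The genes that fell furthest included wali5, first described as induced by aluminium, at −6.32 ± 0.16 (−4.33), the senescence-associated protein SAP at −5.43 ± 0.07 (−3.96), wali6 at −5.26 ± 0.05 (−3.55) and ASN1 at −4.54 ± 0.04 (−2.68). Of these genes 1-FFT had the largest adjusted p, 3.64e-06 over 12 arrays and 0.349 over 16 arrays.

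Of the photosynthetic lists in Nadro, those of light harvesting, the photosystems, photoprotection and the Calvin cycle rose, and that of chlorophyll synthesis did not pass (9 rose and 5 fell of 24, the same adjusted over the list alone; camera adjusted p = 0.385 over 12 and 0.282 over 16 arrays, and adjusted p = 0.608 with an estimated correlation). Light-harvesting genes rose, 24 of 40 against 2 that fell (the same counts adjusted over the list alone), with a median of 0.57 (0.49 over 16 arrays; camera adjusted p = 7.28e-05, and adjusted p = 0.351 with an estimated correlation). The antenna protein CP29 rose by 2.25 ± 0.07 (1.77). Photosystem and electron transport genes rose, 72 of 97 against 7 (the same adjusted over the list alone; median 0.91 and 0.56, camera adjusted p = 5.2e-11, and adjusted p = 0.323 with an estimated correlation). Ferredoxin-NADP(H) oxidoreductase was at 2.63 ± 0.06 (1.99). Of 14 photoprotection genes, 11 rose and 0 fell, also over the list alone (median 1.5, and 1.1 over 16 arrays; camera adjusted p = 2.18e-05, and adjusted p = 0.351 with an estimated correlation). Of 19 Calvin cycle genes, 12 rose and 2 fell, also over the list alone (median 0.70 and 0.54; camera adjusted p = 0.00365, and adjusted p = 0.323 with an estimated correlation). Starch genes rose, 20 of 32 against 5 (the same over the list alone; median 0.32 and 0.21, camera adjusted p = 0.00617, and adjusted p = 0.441 with an estimated correlation). Starch synthase I was at 2.17 ± 0.07 (1.51). The list of fructan and soluble sugar genes passed over 16 arrays (median 0.14, camera adjusted p = 0.0416, and adjusted p = 0.810 with an estimated correlation) but not over 12 (22 rose and 12 fell of 43, the same adjusted over the list alone; camera adjusted p = 0.0558, and adjusted p = 0.457 with an estimated correlation). Phenylpropanoid and flavonoid genes rose, 25 of 38 against 2 (the same over the list alone; median 0.56 and 0.38, camera adjusted p = 2.18e-05, and adjusted p = 0.323 with an estimated correlation). Cytosolic ribosomal protein genes fell, 107 of 135 against 1 (108 and 1 adjusted over the list alone; median −0.62 and −0.46, camera adjusted p = 1.18e-15, and adjusted p = 0.35 with an estimated correlation). Here too markers of dividing cells fell, 31 of 56 against 7 (the same over the list alone; median −0.19, camera adjusted p = 0.00365 over 12 and 0.0569 over 16 arrays, and adjusted p = 0.351 with an estimated correlation). Vascular and cell wall markers rose, 34 of 68 against 14 (34 and 15 over the list alone; median 0.13, camera adjusted p = 0.0262 over 12 and 0.221 over 16 arrays, and adjusted p = 0.605 with an estimated correlation). Cold-regulated, dehydrin and LEA genes fell over 12 arrays, 39 of 73 against 11 (the same over the list alone; median −0.27, camera adjusted p = 0.00722, and adjusted p = 0.672 with an estimated correlation). Over 16 arrays that list's median was −0.04 and its camera adjusted p 0.615.

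Over 12 arrays 14993 probes passed in Nadro, 7630 higher under normal light and 7363 lower, of which 1421 and 1068 by at least 2-fold. Over 16 arrays 0 passed in limma, 7591 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.15. Named genes with the smallest p there, which did not pass, were zip1 (log2 1.02 ± 0.06), a chlorophyll a/b-binding protein (1.09 ± 0.07), the defence protein WIR1A (0.76 ± 0.06), protochlorophyllide reductase B (0.73 ± 0.06) and Wali3 (−1.33 ± 0.12). Leaving out low-light Nadro replicate 1 gave 9126 over 12 arrays, and leaving out low-light Emese replicate 1 gave 3767 over 16 arrays.

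**Figure D2:**
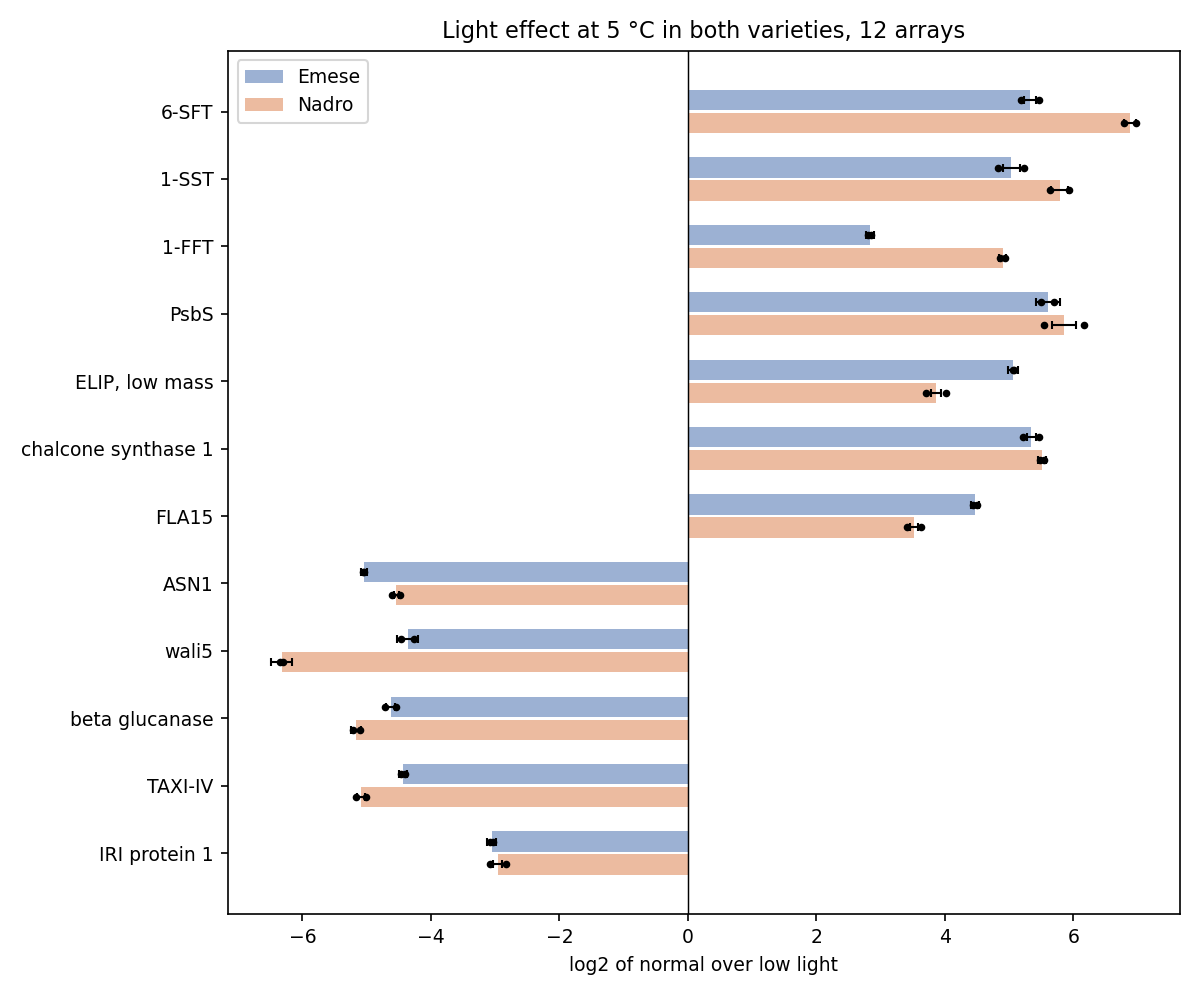
Log2 ratio of normal over low light (horizontal axis) for 12 named genes in Emese and Nadro over 12 arrays. Bars are the estimate, error bars its SE and points the 2 replicates. The fructan enzyme 6-SFT stands at 5.32 in Emese and 6.88 in Nadro, and ASN1 at −5.05 and −4.54.

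**Figure D3:**
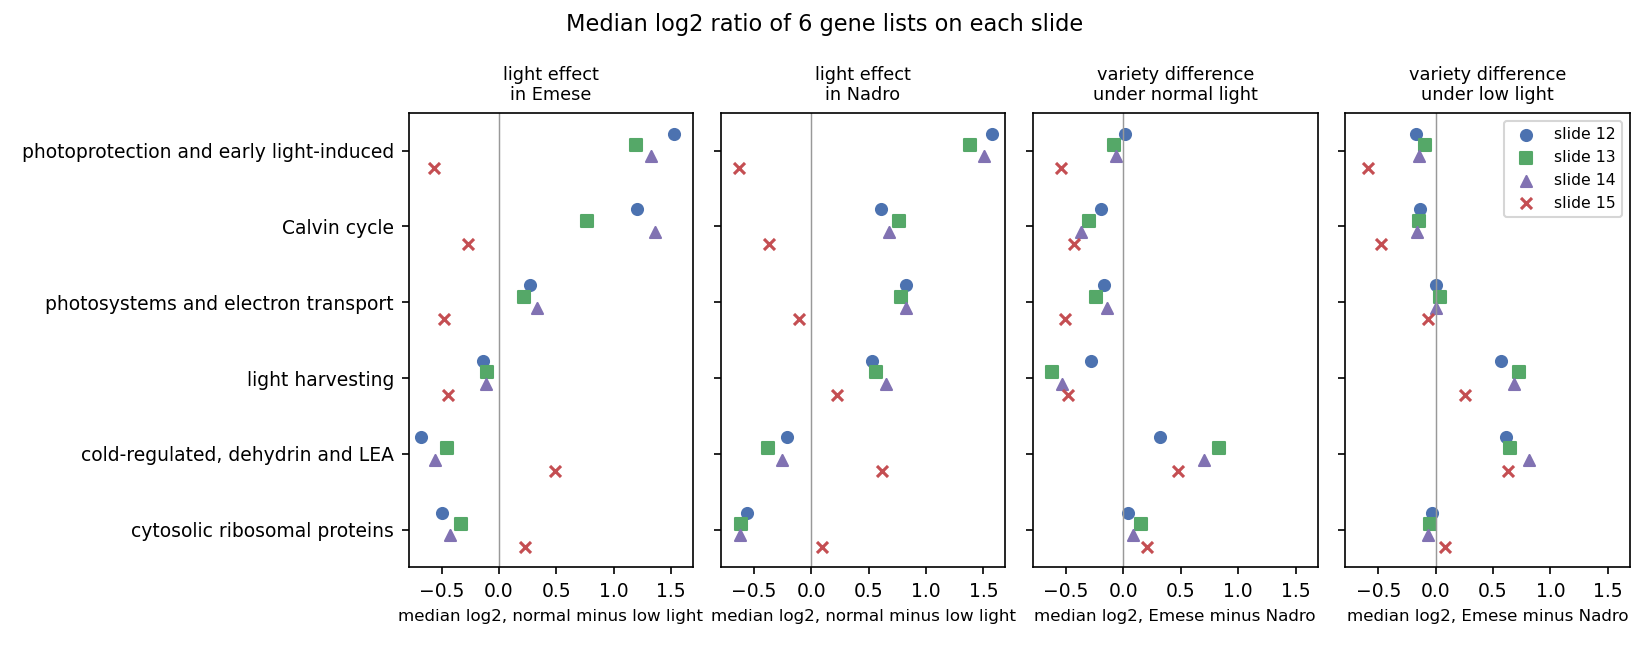
Median log2 ratio of 6 gene lists (horizontal axis, normal minus low light or Emese minus Nadro) with the loop solved for each slide alone. Slides 12 and 15 hold replicate 1, slides 13 and 14 replicate 2. In the light effects of both varieties slide 15 stands apart from the other slides for most lists, while the variety difference of the cold-regulated list is above 0 on slides 12 to 14 in both lights. The values of slide 15 are solved as labelled and, with 3 arrays off their label, do not measure these contrasts. Each slide holds 1 dye orientation, so its values also carry the dye effect of the probes.

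Between the varieties under normal light, Emese held more transcript of cold-regulated proteins and less of the photosynthetic antenna. The cold acclimation protein WCS120, a dehydrin-type protein induced in the cold, was higher in Emese by 4.05 ± 0.29 on the log2 scale (4.10 over 16 arrays), another dehydrin by 3.10 ± 0.18 (3.00), Wcs66 by 2.68 ± 0.12 (2.69), ice recrystallization inhibition protein 2 by 2.71 ± 0.22 (2.39) and Wcor80 by 2.30 ± 0.17 (2.16). In all, 47 of 73 cold-regulated, dehydrin and LEA genes were higher in Emese and 5 lower (50 and 5 adjusted over the list alone; median 0.53 and 0.64 over 16 arrays, camera adjusted p = 7.21e-15 and 1.97e-11). The adjusted p was 0.406 with an estimated correlation. Light-harvesting genes were lower in Emese, 24 of 40 with 0 higher (the same over the list alone; median −0.45 and −0.49, camera adjusted p = 4.03e-09, and adjusted p = 0.323 with an estimated correlation). CP29 was at −1.50 ± 0.14 (−1.45). Photosystem and electron transport genes were lower too, 48 of 97 against 11 higher (49 and 11 over the list alone; median −0.22 and −0.29, camera adjusted p = 1.07e-05, and adjusted p = 0.323 with an estimated correlation). Of 24 chlorophyll synthesis genes, 10 were lower and 0 higher (13 and 0 over the list alone; median −0.15 and −0.12, camera adjusted p = 0.000177, and adjusted p = 0.323 with an estimated correlation). The large subunit of ribulose bisphosphate carboxylase, the enzyme that fixes carbon dioxide, was lower at −2.03 ± 0.19 (−1.84), with the same sign on all 16 other probes of that name. Vascular and cell wall markers were higher in Emese, 22 of 68 against 5 (22 and 6 over the list alone; median 0.08 and 0.06, camera adjusted p = 6.88e-05 over 12 and 0.00989 over 16 arrays, and adjusted p = 0.457 with an estimated correlation). Markers of dividing cells were lower, 8 of 56 with 0 higher (7 and 0 over the list alone; median −0.06 and −0.01, camera adjusted p = 0.0386 over 12 and 0.438 over 16 arrays, and adjusted p = 0.406 with an estimated correlation). A difference in the share of such cells was not separated here either. Probes of 1 name did not always go the same way, since an acyl-CoA-binding protein was at −3.85 ± 0.07 on 1 probe and 2.83 ± 0.32 on another, and 60S ribosomal protein L9 at −1.92 ± 0.24 and 1.46 ± 0.06.

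The test over 12 arrays passed 5688 probes, 2743 higher in Emese and 2945 lower, of which 282 and 144 by at least 2-fold. Over 16 arrays 0 passed in limma, 2757 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.258. Named genes with the smallest p there, which did not pass, were PsbO (log2 −0.95 ± 0.05), the aspartic proteinase phytepsin (−0.88 ± 0.06), hydroxyphenylpyruvate reductase (−0.43 ± 0.04), PsbP (−0.65 ± 0.06) and protochlorophyllide reductase B (−0.69 ± 0.07). The count over 12 arrays depended on which extract was left out. It fell most without low-light Nadro or low-light Emese replicate 1, neither of which is in this contrast. Replicate 1 then rests on the slide 12 array of normal-light Emese against normal-light Nadro alone. Of the 12 arrays that one matched its label least (0.638). The count fell less without a normal-light extract of replicate 2 and did not fall without one of replicate 1.

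Under low light the cold-regulated genes were again higher in Emese. The dehydrin was higher by 4.70 ± 0.18 (4.46 over 16 arrays), WCS120 by 3.91 ± 0.29 (3.80), DHN14 by 3.75 ± 0.11 (3.43), Wcor80 by 3.64 ± 0.17 (3.47) and the LEA D-11 dehydrin by 3.62 ± 0.05 (3.38). In the list, 46 of 73 were higher and 5 lower (50 and 5 adjusted over the list alone; median 0.67 and 0.74, camera adjusted p = 1.37e-11 and 2.29e-10, and adjusted p = 0.441 with an estimated correlation). A class III peroxidase (peroxidase 62) was higher by 4.95 ± 0.30 (4.73), a glutathione transferase by 3.69 ± 0.16 (3.37), an endochitinase by 2.78 ± 0.06 (2.63) and 1-FFT by 2.72 ± 0.06 (2.05). Light-harvesting genes were higher in Emese here, 27 of 40 against 2 lower (28 and 2 over the list alone; median 0.66 and 0.64, camera adjusted p = 3.39e-07, and adjusted p = 0.323 with an estimated correlation). Fructan and soluble sugar genes were higher, 24 of 43 against 7 (the same over the list alone; median 0.28 and 0.19, camera adjusted p = 0.00133 over 12 and 0.153 over 16 arrays, and adjusted p = 0.351 with an estimated correlation). Lower in Emese were germin-like protein 2a at −2.59 ± 0.06 (−2.30), the reticulon at −2.82 ± 0.09 (−2.54) and the cold-response factor CBFIVd-A22 at −1.57 ± 0.06 (−1.45). The list of CBF and DREB factors, the regulators of cold-induced genes, did not pass (8 higher and 11 lower of 27, camera adjusted p = 0.696; 9 and 11 adjusted over the list alone; adjusted p = 0.735 with an estimated correlation). Root and seed markers were lower in Emese, with medians of −0.17, −0.12 and −0.26 on slides 12, 13 and 14. A difference in the share of such cells was not separated under low light.

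The test over 12 arrays passed 9927 probes, 5067 higher in Emese and 4860 lower, of which 508 and 295 by at least 2-fold. Over 16 arrays 0 passed in limma, 5445 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.0793. Named genes with the smallest p there, which did not pass, were zip1 (log2 1.41 ± 0.06), a dehydration response element binding protein (−0.98 ± 0.06), a proline-rich protein (1.33 ± 0.08), WIR1A (0.90 ± 0.06) and a heat shock protein of the HSP70 type (0.81 ± 0.05). Over 12 arrays the count was 1519 without low-light Emese replicate 1 and 1246 without low-light Nadro replicate 1.

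**Figure D4:**
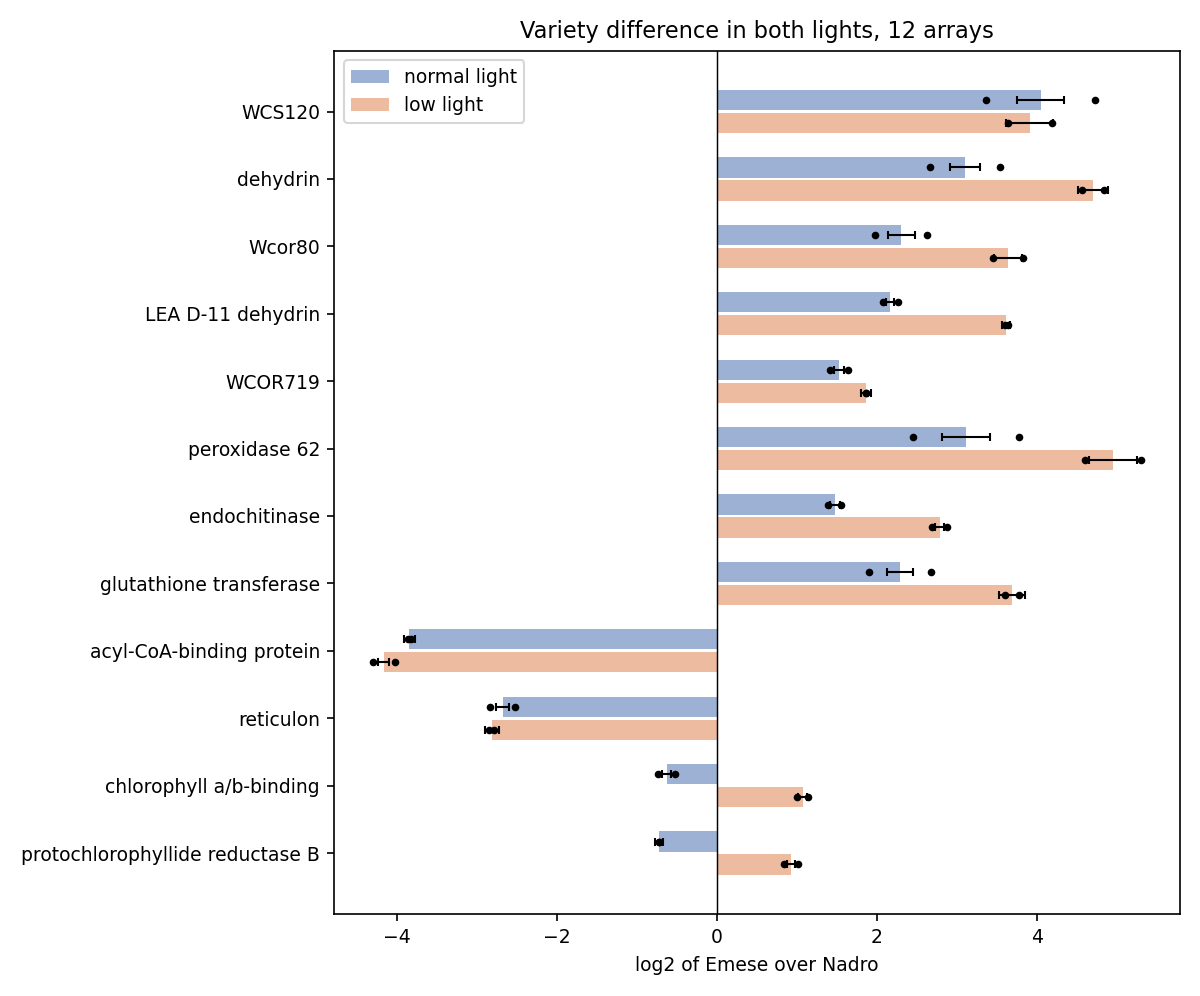
Log2 ratio of Emese over Nadro (horizontal axis) under normal and low light for 12 named genes over 12 arrays. Bars are the estimate, error bars its SE and points the 2 replicates. WCS120 stands at 4.05 and 3.91, and protochlorophyllide reductase B at −0.73 under normal and 0.92 under low light.

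The light effect differed between the varieties for the light-harvesting genes. In this test of the difference (the light effect in Emese minus that in Nadro), 27 of 40 were negative and 0 positive (27 and 1 adjusted over the list alone), with a median of −1.10 over 12 arrays and −0.95 over 16. The camera adjusted p was 8.66e-13 and 2.48e-16, and the adjusted p was 0.323 over 12 and 0.810 over 16 arrays with an estimated correlation. The antenna protein CP24 was at −2.94 ± 0.08 (−2.88), CP29 at −2.29 ± 0.10 (−2.25) and a chlorophyll a/b-binding protein at −1.68 ± 0.06 (−1.57). Protochlorophyllide reductase B, which makes chlorophyllide in the light, was at −1.65 ± 0.07 (−1.63). Chlorophyll synthesis genes as a list were negative, 7 of 24 with 0 positive (8 and 0 over the list alone; median −0.19 and −0.17, camera adjusted p = 0.00134, and adjusted p = 0.323 with an estimated correlation). So were photosystem and electron transport genes, 41 of 97 against 11 (43 and 14 over the list alone; median −0.20 and −0.18, camera adjusted p = 7.28e-05, and adjusted p = 0.323 with an estimated correlation). Phosphoethanolamine methyltransferase, an enzyme of choline synthesis, was at −2.64 ± 0.07 (−2.46), with the same sign on all 12 other probes, and zip1 at −2.08 ± 0.07 (−1.97). 1-FFT was at −2.07 ± 0.09 (−2.08), since its rise was 2.83 ± 0.06 in Emese and 4.90 ± 0.06 in Nadro. Positive were germin-like protein 2a at 2.37 ± 0.08 (2.28) and CBFIVd-A22 at 1.15 ± 0.08 (1.18). Cytosolic ribosomal protein genes were positive, 37 of 135 against 2 (43 and 3 over the list alone; median 0.15 and 0.17, camera adjusted p = 2.07e-08, and adjusted p = 0.397 with an estimated correlation). Vascular and cell wall markers had a median of 0.12 over 16 arrays, and root and seed markers 0.25. A difference in the share of such cells was not separated in the interaction.

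The test over 12 arrays passed 5339 probes in the interaction, 2432 positive and 2907 negative, of which 384 and 305 by at least 2-fold. Over 16 arrays 0 passed in limma, 2524 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.110. Named genes with the smallest p there, which did not pass, were zip1 (log2 −1.95 ± 0.08), protochlorophyllide reductase B (−1.43 ± 0.08), a chlorophyll a/b-binding protein (−1.62 ± 0.11), PsbO (−1.10 ± 0.08) and hydroxyphenylpyruvate reductase (−0.73 ± 0.05). For zip1, protochlorophyllide reductase B and the chlorophyll a/b-binding protein these are other probes of the name than those given above for this contrast. Within 1 dye orientation a loop cannot separate this contrast from the dye. The light effect in each variety and the variety difference in each light carry the dye effect there too. Over 12 arrays replicate 1 took its dye effect from replicate 2 in every comparison. The count over 12 arrays was 49 without low-light Nadro replicate 1, 72 without low-light Emese replicate 1, 2595 without normal-light Emese replicate 2 and 3058 without normal-light Nadro replicate 2.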

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

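The tests of wrong labels and of replicate 1 plants, the 2 tests of dye or slide and the 2 tests of unequal binding were chosen after the result was seen, while those of dim signal and cross-hybridisation were chosen before.

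Array by array, 61 groups of 4 arrays were tested for 1 array far from the others, and 11 had such an array, all 11 on slide 15, where 3.05 would be expected by chance at 1 in 20. The groups are not independent of each other. Of the 11, 9 were list medians on arrays already seen to be off their label, for lists picked on a fit that holds those arrays. The excess over 3.05 therefore restates the label check and is not separate evidence. In the light effect of Emese, the array of replicate 1 on slide 15 had a median log2 of −0.63 for photosystem and electron transport genes (0.25 to 0.39 on the other 3 arrays), −0.99986 for photoprotection (1.14 to 1.55), 0.20 for cold-regulated genes (−0.58 to −0.49) and 0.42 for cytosolic ribosomal proteins (−0.45 to −0.35). In the light effect of Nadro, the array of that slide had 0.00554 for photosystem and electron transport genes (0.80 to 0.83), −0.0369 for photoprotection (1.40 to 1.49), −0.22 for the Calvin cycle (0.73 to 0.81), 0.00124 for heat shock proteins (−0.16 to −0.13) and −0.0624 for cytosolic ribosomal proteins (−0.64 to −0.59). The array labelled low-light Emese against low-light Nadro on slide 15 had a median green intensity of 35.5 (40.0 to 40.7 on the others) and 41.9% of green spots well above background (54.4 to 56.4).

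For these 3 arrays, wrong labels or exchanged extracts predict that each follows another pair of conditions closely. Their highest correlations with another pair were 0.915 to 0.960 across probes, which fits. The best pairs were normal against low light in Nadro, low against normal light in Emese and low-light Emese against low-light Nadro, the same 3 pairs in another order. That order is a hypothesis read from these same correlations, and the sources hold no record of an exchange to check it against. Dim signal predicts that the arrays return to their label over bright probes, but over 14204 probes well above background on all arrays the highest correlation with the label was 0.229, which this explanation does not predict. Plants of replicate 1 that responded otherwise would also show on slide 12, where the same extracts were hybridised, but there the lowest correlation of those 3 pairs with replicate 2 was 0.961.

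The light effect differed between the varieties, by camera on the interaction over 16 arrays, for 9 lists, none of which passed with an estimated correlation. The medians were −0.95 for light harvesting, −0.18 for photosystems and electron transport, −0.17 for chlorophyll synthesis, −0.11 for starch, −0.0482 for pathogenesis-related genes (−0.04 with a camera adjusted p of 0.148, which does not pass, without the 36 members matched only inside another word), 0.0889 for lipid transfer proteins, 0.17 for cytosolic ribosomal proteins, 0.12 for vascular and cell wall markers and 0.25 for root and seed markers.

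For light harvesting, a dye effect would turn the sign between the dye orientations of replicate 2, but the medians there were −1.26 and −1.12. Probes that bind the transcripts of the varieties unequally, by a fixed factor, would give the same difference in both lights and no interaction. The median was −0.45 under normal and 0.66 under low light, a change of 1.101. That change restates the interaction by which the list was picked, so it is not separate evidence against unequal binding. Probes shared by near-identical gene copies would make the members move together, and the median correlation of member pairs over the 8 extracts was 0.418 (quartiles −0.05 and 0.82), which genes regulated together would also give, so this cannot be told. A rise with light in Nadro alone, a high level in Emese under low light and a low one under normal light describe the same 4 conditions. They are views of the same result, not rival readings, and what causes it was not tested.

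For cold-regulated, dehydrin and LEA genes, higher in Emese in both lights, a dye or slide effect would leave some slide near or below 0, but the lowest median over slides 12 to 14 and both lights was 0.319 and the highest 0.83. Unequal binding alone, by a fixed factor, would leave the difference equal in both lights, and 45.9% of the called members (28 of 61) passed the interaction test over 12 arrays. A fixed factor cancels in that test and can stand beside a real interaction. The test therefore cannot exclude unequal binding for any member, so this cannot be told. Some probes of 1 gene name went opposite ways between the varieties, such as those of the acyl-CoA-binding protein. Whether such probes bind the varieties unequally or report different gene copies was not tested.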

How the results depend on the processing

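All figures here are counts of probes past the threshold in the order light effect in Emese, light effect in Nadro, variety difference under normal light, variety difference under low light and interaction, and over 16 arrays the fit written before the data were examined gave 0 in each. The settings over 12 or 13 arrays were chosen after the result was seen. The count stayed 0 in all 5 with no background correction, background subtraction by limma's minimum method, Aquantile, no filter on dim probes, a filter on all 16 arrays, marked spots kept, or a 2-fold threshold added. Aquantile leaves the ratios unchanged and a fold threshold can only remove calls, so those outcomes were fixed in advance. An adjusted p under 0.1 gave 2093 under low light (0 at 0.05). The scanner software's processed signals, median centred without loess, gave 224 (214 higher, 10 lower), 0, 984 (731, 253), 991 (657, 334) and 189 (176, 13). Median centring gave 20 in the interaction, the series matrix values 263, a robust and trended prior 507 and normexp with offset 0 586 in the variety difference under low light. Fitting the 8 averaged ratios as a loop, which treats ratios that share an extract as independent, gave 6408, 7428, 21, 4531 and 2075. Treating all 16 arrays as replicates, which counts technical repeats, gave 7649, 8360, 1167, 5511 and 2964. Slide-wise values with the extract as random block gave 1548, 1244, 679, 4073 and 544. There the estimated correlation between slides of an extract was −0.0974, so slides counted as if independent. The cause of each shift was not tested.

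Without slide 15 the counts were 16491, 14993, 5688, 9927 and 5339, and with at least 2-fold 2270, 2489, 426, 803 and 689. Without the 3 arrays that did not follow their label they were 17010, 15408, 7217, 10780 and 6470. With slide 15 left out, offset 0 gave 16424, 15264, 4007, 8584 and 3028, processed signals with median centring in place of normexp and loess 15914, 14442, 7726, 8515 (61.4% higher, against 51.0%) and 4181 (36.3%, against 45.6%), the series matrix values 17691, 16428, 9972, 11205 and 6753, arrays as replicates 18480, 16752, 9409, 12819 and 10551, no dye correction 16537, 14666, 4485, 10010 and 5129, and a robust and trended prior 17230, 15648, 6153, 10401 and 5896. For the probes called over 12 arrays, the median ratio of the log2 over 16 arrays to that over 12 was 0.665, 0.673, 0.905, 0.847 and 0.918.

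Replicate numbers are shared between conditions. Same-numbered extracts deviated together only in part, with correlations across probes of −0.30 to 0.63 over 16 arrays and 0.09 to 0.43 over 12. With no replicate block, on single channels, the counts were 5898, 6678, 4, 1 and 53 over 16 arrays and 15276, 14084, 5787, 8954 and 4259 over 12.

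Leaving out each extract in turn, with the lone extract of a condition assumed to vary like the others, gave 0 throughout over 16 arrays except 0 to 3767 in the light effect of Nadro. Over 12 arrays it gave 9242 to 16011, 9126 to 14748, 0 to 6409, 1246 to 10545 and 49 to 5110.

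Of 150 list tests, 7 lost and 16 gained the call without slide 15, and 127 stayed on their side of the threshold. Of those 127, 17 medians with no call over either set of arrays changed sign and 110 kept it. All 150 stayed with marked spots kept. They also stayed with Aquantile or a robust prior, but neither changes the values that camera uses, so that was fixed in advance. With an estimated correlation 50 lost the call. Without the members matched only inside another word 4 lost it over 16 arrays: pathogenesis-related and defence, light effect in Nadro and interaction of light and variety, whose members changed, and phenylpropanoid and flavonoid, light effect in Emese, and photorespiration, light effect in Nadro, whose members did not and whose adjusted p moved only through the adjustment over all lists, to 0.0501. Over all settings 18 medians with a call on either side changed sign. In 3 of them the direction of the test turned with it, or there was no test. For cytosolic ribosomal proteins, variety difference under low light, it was 0.12 without low-light Nadro replicate 2, against −0.01, and −0.252 without replicate 1. For cold-regulated, dehydrin and LEA, light effect in Nadro, it was 0.0801 without normal-light Nadro replicate 2, against −0.04, and −0.412 without replicate 1. For cold-regulated, dehydrin and LEA, light effect in Emese, it was 0.00698 with dye set 1 alone, against −0.30. In the other 15 camera kept its direction, which follows the members' moderated statistics rather than their median. Among these, photosystems and electron transport, interaction of light and variety, went from −0.18 to 0.0363 without normal-light Emese replicate 1 and 0.0398 without low-light Nadro replicate 2, starch in the interaction from −0.11 to 0.00995 without the latter, and vascular and cell wall markers, variety difference under normal light, from 0.06 to −0.00216 without normal-light Emese replicate 2, each losing the call. The cause was not tested. Of 457 named results, most of them chosen on the fit over 12 arrays, 456 passed without slide 15 and not with it. Signal was well above background in both channels for at most 38.9% of spots on slide 15, and probes under the filter were not tested.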

Other observations

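Values here are from the fit over 12 arrays, which was chosen after the result was seen. Jasmonate genes rose under normal light in both varieties, 17 of 22 with 0 falling in each, also adjusted over the list alone (median log2 0.39 in Emese and 0.47 in Nadro, camera adjusted p = 6.88e-05 and 6.42e-05, and adjusted p = 0.323 with an estimated correlation). A ZIM domain protein of that list rose by 1.26 ± 0.05 and 1.27 ± 0.05. Heat shock and chaperone genes fell, 51 of 98 against 17 in Emese and 50 against 13 in Nadro (52 and 17, and 52 and 13, over the list alone; median −0.14 and −0.17, camera adjusted p = 0.00461 and 0.00225, and adjusted p = 0.323 with an estimated correlation).

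Glutathione S-transferases rose in Nadro, 29 of 48 against 12 (the same over the list alone; median 0.34, camera adjusted p = 0.0145, and adjusted p = 0.443 with an estimated correlation), with a glutathione S-transferase at 2.41 ± 0.05. Photorespiration genes rose in both, 8 of 14 against 2 in Emese and 9 against 2 in Nadro (the same over the list alone; median 0.40 and 0.57, camera adjusted p = 0.0489 and 0.0164, or 0.127 and 0.0481 over 16 arrays, and adjusted p = 0.351 with an estimated correlation). Lipid transfer protein genes rose in Emese, 28 of 44 against 10 (the same over the list alone; median 0.26, camera adjusted p = 0.00472, and adjusted p = 0.441 with an estimated correlation). Starch genes rose in Emese, 15 of 32 against 4 (14 and 4 over the list alone; median 0.15, camera adjusted p = 0.0262 and 0.182 over 16 arrays, and adjusted p = 0.497 with an estimated correlation). Plastid ribosomal protein genes fell in Emese, 21 of 39 against 9 (the same over the list alone; median −0.18, camera adjusted p = 0.0326 and 0.104 over 16 arrays, and adjusted p = 0.514 with an estimated correlation).

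Pathogenesis-related and defence genes were higher in Emese under normal light, 33 of 108 against 11 (38 and 13 over the list alone; camera adjusted p = 0.000126), and under low light, 55 against 12 (58 and 14 over the list alone; camera adjusted p = 1.73e-05), each with adjusted p = 0.351 with an estimated correlation. That list holds 36 members matched only inside another word, and without them the medians were 0.09 and 0.15 with camera adjusted p = 0.000136 and 0.000268. Abscisic acid genes were higher in Emese under low light, 16 of 28 against 5 (17 and 5 over the list alone; median 0.16, camera adjusted p = 0.0357 and 0.0707 over 16 arrays, and adjusted p = 0.351 with an estimated correlation). Cytokinin genes, 6 measured, were lower there, 5 against 1 (the same over the list alone; median −0.54, camera adjusted p = 0.034 and 0.441 over 16 arrays, and adjusted p = 0.351 with an estimated correlation). Root and seed markers went opposite ways in the 2 lights. They were higher in Emese under normal light, 12 of 41 against 4 (13 and 5 over the list alone; median 0.08, camera adjusted p = 0.00983 and 0.000715 over 16 arrays, and adjusted p = 0.441 with an estimated correlation), and lower under low light, 19 against 4 (the same over the list alone; median −0.20, camera adjusted p = 0.000469, and adjusted p = 0.351 with an estimated correlation), with germin-like protein 2a among them. They rose with light in Emese, 25 against 11 (25 and 12 over the list alone; median 0.27, camera adjusted p = 0.0386, and adjusted p = 0.497 with an estimated correlation). In the interaction they were positive, 20 against 4 (23 and 5 over the list alone; median 0.29, camera adjusted p = 3.22e-06, and adjusted p = 0.35 with an estimated correlation). The pseudo-response regulator PRR95 of the circadian clock fell by −1.49 ± 0.04 in Nadro and was at 0.97 ± 0.06 in the interaction.

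Lists that passed in no comparison over 12 arrays, with the smallest camera adjusted p, were CBF and DREB factors (0.134), antioxidant enzymes (0.131), gibberellin (0.777), auxin (0.143), ethylene (0.459), photoreceptors and clock (0.0662), dark and starvation (0.155), and vernalization and flowering (0.0505, and 0.0404 over 16 arrays in the light effect in Emese, which passes). The list of epidermis and wax markers had 3 measured genes and was not tested. The other 7 tested lists among them passed in no comparison over 16 arrays either, and none passed with an estimated correlation. Over 16 arrays 0 probes passed, and of the 15, 14, 10, 10 and 10 lists that passed camera over 12 arrays (light in Emese, light in Nadro, variety under normal light, variety under low light, interaction), 11, 11, 9, 4 and 8 passed camera there, all in the same direction. Passing over 16 arrays alone were also pathogenesis-related genes in the light effect in Nadro (camera adjusted p = 0.0372, or 0.383 without the 36 members matched only inside another word, and 0.702 with a median of −0.00245 without them over 12 arrays), starch between the varieties under normal light (0.0298) and lipid transfer proteins in the interaction (0.0188), with adjusted p = 0.810, 0.821 and 0.810 with an estimated correlation.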
